A study of Mus musculus with 21 samples.

How the data were processed

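The authors' deposited table holds one value per gene and library in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library, per the file headers), printed to 2 decimals, with group means that equalled the means of the library values within 0.0007. The authors' deposited log2 fold changes, p values and q values for pairs of groups stand in the same table. The submitters' processing notes name the mouse genome build mm10, HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12, without the role or order of each. Of 22135 genes, 19285 had FPKM values and 2850 had none. A spreadsheet had turned 27 symbols into dates, and these were restored from the Entrez gene identifier. Coordinates are those of the authors' deposited table, taken as 1-based on mm10. The RefSeq gene table, used to restore symbols, held 22048 of the identifiers. Summary columns of a group named ET1, which has no sample in the series, were not used.

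FPKM values were taken as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, which left 14444. All 21 libraries entered one limma model with a mean for each of the 7 groups, a mean-variance trend and 14 residual degrees of freedom. A gene was called when its two-sided p value, adjusted by the Benjamini-Hochberg method within a comparison, was under 0.05 and its absolute log2 fold change was at least 1. Fold changes are PTM minus the other group, and the added 1 shrinks them where FPKM is low. Genes called in the same direction in all 6 comparisons were counted, as were genes higher in PTM and each smooth muscle group than in each of Sertoli, Leydig and germ cells. The numbers to set beside those counts came from 50 simulations of unchanged groups against the same PTM libraries.

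The lists of genes numbered 31: 12 cell programmes, 17 sets of cell type markers and 2 sets of check genes. They were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists with at least 3 tested members, and again with the correlation estimated from the data. Members were also counted with p values adjusted over the list alone. Except for macrophage markers against Sertoli cells and niche factors against vascular cells, these counts equalled those from adjustment over all tested genes.

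The test, the lists, the sets, most alternatives and the rule for naming genes were fixed before the data were examined. Under that rule the text names, for each comparison, up to 6 called genes at each extreme of the fold change with non-overlapping libraries and at least 10 FPKM in the higher group. Symbols that are only model numbers are left out. It also names, under the same conditions, up to 15 genes of the set higher in PTM than all 6 groups, up to 4 members per list and comparison, and 12 fixed marker genes. With 3 libraries against 3, groups fail to overlap for 10% of genes by chance.

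No read counts were available, so depth was inferred from the size of 1 read in FPKM. Over transcripts of 800 to 1500 bases, with 150 bases taken off, 376 to 594 low values per library entered this estimate, and 83.6 to 91.4% of them were whole reads within 0.2, against 40% by chance. Variance between libraries of a group, as a ratio to sampling noise over genes of 200 to 1000 reads, was 1.46 to 1.64 in VSMC, 1.18 to 1.69 in ISMC and 1.34 to 1.79 in TSMC. It was 1.94 to 11.45 in PTM, 2.37 to 22.42 in Sertoli, 10.92 to 22.3 in Leydig and 1.47 to 8.59 in germ cells. Replicate 2 stood apart in PTM, Sertoli and germ cells. On this ratio Sertoli replicate 2 was at 17.62 and 22.42 from the other Sertoli libraries, and at 16.74 to 21.1 from PTM libraries. Its Pearson correlations of log2(FPKM + 1) were nonetheless higher with Sertoli (0.9717 and 0.9797) than with PTM libraries (0.9625 to 0.9677). Neither the labels nor the series text say that replicates are separate cultures or animals, so the p values measure the spread between these libraries, which may be technical. That spread is pooled over the 7 groups. Smooth muscle libraries vary least, so the pooled value can understate the spread within Sertoli and Leydig cells.

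The labels give no pairing between groups. Deviations of same-numbered libraries from their group means correlated at 0.227, 0.25 and 0.103 between PTM and Sertoli, and this was the 1 pair of groups of 21 in which all 3 exceeded 0.1. A fit with replicate number as a block was therefore added for that pair.

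The procedure was tested on simulated data with 50 genes at each planted change. It recovered 48, 48, 49 and 49 of them at log2 fold changes of 1.5, 2, -1.5 and -2, and called 1 of 14244 unchanged genes. Of 20 unchanged lists, 0 were called, and 1 changed list was. Changes were planted only in genes well above the filter in PTM, so recovery of weakly expressed genes was not tested. The simulated noise was independent between genes, with 1 spread per gene for all groups. The real groups differed in spread, so the rates of recovery and false calls hold for equal spreads only. Estimated correlations in the real lists reached 0.823 (cell cycle), so the simulation does not test the preset correlation for genes that vary together. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Some genes are not reported here.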

Results

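RNA was sequenced from mouse cells held in culture, in 7 groups of 3 libraries each. Peritubular myoid cells (PTM), the flat contractile cells that wrap the seminiferous tubule, were set beside Sertoli cells, which line the tubule and nurse the germ cells, steroid-producing Leydig cells of the interstitium, and germ cells. The remaining groups were smooth muscle cells of blood vessel (VSMC), intestine (ISMC) and trachea (TSMC). According to the series text, the testicular cells were isolated by cited methods and the smooth muscle cells came from a commercial supplier, so tissue of origin and source of the cells cannot be told apart in comparisons of PTM with the smooth muscle groups. The mice were C57BL/6J, cells grew in DMEM/F12 medium with 10% serum, and total RNA was sequenced. Depth inferred from the FPKM values was 20200000 to 22600000 fragments per library, with a median of 21500000. Each library had 10160 to 11536 genes at 1 FPKM or more, and its 10 most abundant genes made up 5.35 to 10.35% of all FPKM. The series title poses the question: how do PTM cells differ from other testicular cells and from smooth muscle of other tissues?

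Across the 14444 tested genes, PTM libraries correlated most strongly with Sertoli libraries (mean Pearson r of log2(FPKM + 1) across genes 0.96, range 0.951 to 0.968 over pairs of libraries). The mean was 0.936 with Leydig, 0.893 with ISMC, 0.887 with VSMC, 0.885 with TSMC and 0.192 with germ cells. Genes are not independent replicates, so these values describe similarity only. An exact two-sided permutation test of one group against another gave p = 0.1 for 14 of the 15 pairs (adjusted p = 0.107) and p = 0.4 for VSMC against TSMC (adjusted p = 0.4). With 20 arrangements of 6 libraries, 0.1 is the smallest p this design allows. Within groups the mean r was 0.99 in PTM, 0.983 in Sertoli, 0.977 in Leydig, 0.995 in germ cells and 0.998 in each smooth muscle group. The first principal component held 75.2% of the variance with germ cells included, and 61.9% without them.

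**Figure D1:**
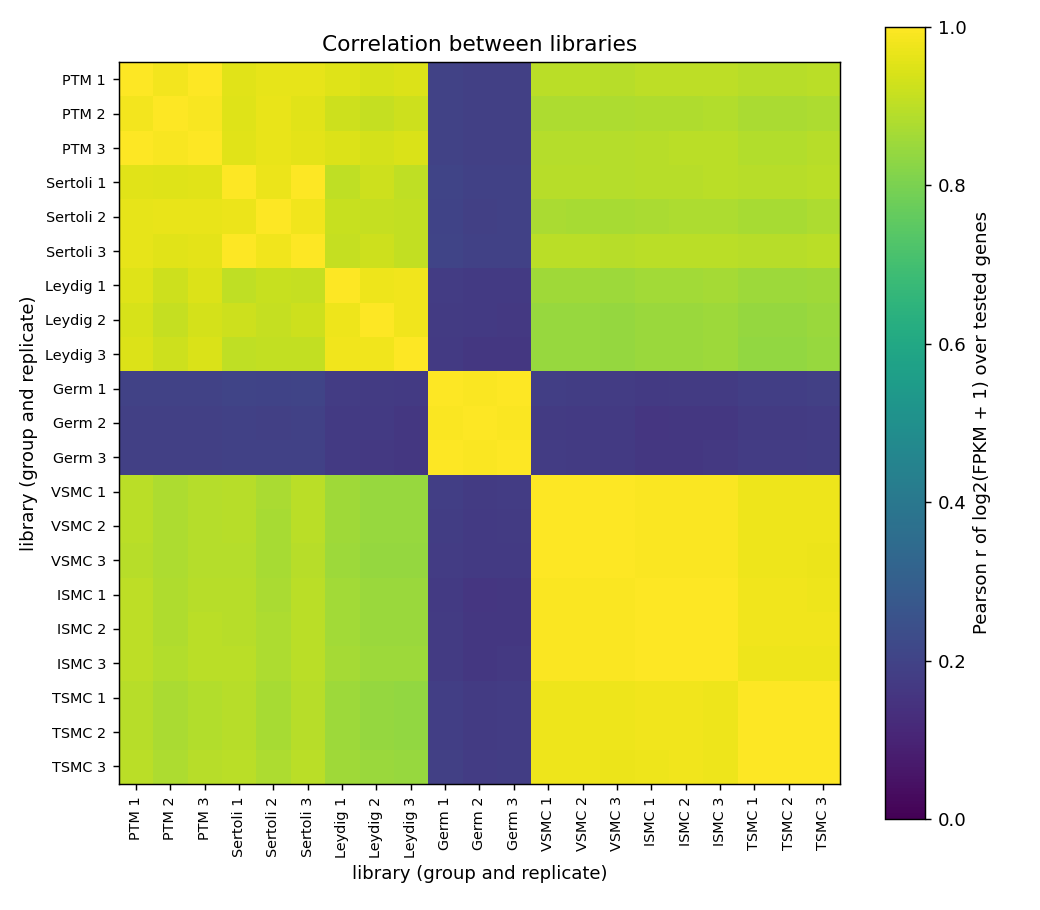
Pearson correlation of log2(FPKM + 1) between each pair of the 21 libraries over 14444 tested genes, from 0 to 1 on the colour scale. Germ cell libraries stand apart from all others, and PTM libraries are nearer to Sertoli (mean 0.96) than to the smooth muscle groups (0.885 to 0.893).

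PTM cells and Sertoli cells share the wall of the tubule, where PTM cells supply contraction and part of the basement membrane, and Sertoli cells build the epithelium and its barrier. Smooth muscle actin (Acta2), transgelin (Tagln), smooth muscle myosin (Myh11), calponin (Cnn1) and desmin (Des) make up the contractile and filament apparatus that usually identifies PTM cells. Sox9 and Wt1 are transcription factors of Sertoli cells, while Insl3, a peptide hormone, and Cyp11a1, which cuts the side chain of cholesterol in the first step of steroid synthesis, belong to Leydig cells. This comparison asks which genes separate the neighbouring cells of the tubule wall.

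Of the contractile list, 0 members were called higher and 13 lower in PTM than in Sertoli libraries, of 25 tested, with the same numbers adjusted over the list alone. This list had the smallest p value of the lists tested (limma camera, adjusted p = 6.95e-16, and adjusted p = 0.0197 with an estimated correlation). Acta2 (Entrez 11475, chromosome 19, 34240336 to 34255373, minus strand) stood at 1605 ± 115 FPKM in PTM and 4332 ± 451 in Sertoli libraries (SD, n = 3), a log2 fold change of -1.43 (SE 0.28, adjusted p = 0.000989). Myh11 was at 48.5 ± 4.51 FPKM in PTM against 221 ± 27.2 in Sertoli libraries (log2 fold change -2.16, adjusted p = 2.82e-07). Des differed by -2.48, Cnn1 by -2.56, Actg2 by -2.86 and Tagln by -1.48 on the log2 scale. Casq2, a calcium store protein of muscle, and Tnnt2, cardiac troponin T, were lower by larger steps of -3.25 and -3.90. Skeletal and cardiac muscle markers had 0 called higher and 2 lower of 8 (adjusted p = 0.00342, and adjusted p = 0.101 with an estimated correlation).

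Leydig markers went the other way, with 9 called higher and 0 lower of 14 tested, likewise adjusted over the list alone (adjusted p = 6.41e-07, and adjusted p = 0.2 with an estimated correlation). Insl3 (Entrez 16336, chromosome 8, 71689252 to 71690577, plus strand) was at 3647 ± 1394 FPKM in PTM and 7.71 ± 1.58 in Sertoli libraries, a log2 fold change of 8.64 (SE 0.73, adjusted p = 1.62e-07). The gene lies within the 3' end of Jak3 on the same strand, which leaves the assignment of overlapping reads uncertain. Cyp11a1 was at 300 ± 94.9 FPKM against 5.89 ± 2.70, and Agt, the angiotensin precursor, at 68.0 ± 28.2 against 2.47 ± 1.01. Star, which carries cholesterol into mitochondria, did not separate the groups (73.1 ± 9.70 against 75.8 ± 2.17 FPKM, log2 fold change -0.06, adjusted p = 0.932). Cyp17a1 was below the filter, at a mean of 0.02 FPKM in PTM, 0.05 in Leydig and 0.823 in germ cells.

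Sertoli markers themselves had 2 called higher and 3 lower of 24, also adjusted over the list alone (adjusted p = 0.0307, and adjusted p = 0.68 with an estimated correlation). That call was lost under either rescaling of the libraries (adjusted p = 0.169 with quantile normalization and 0.221 with median log-ratio scaling). The numbers were 1 higher and 5 lower without PTM replicate 2, and 4 and 3 without Sertoli replicate 2. Sox9 was at 36.6 ± 21.4 FPKM in PTM and 49.0 ± 7.05 in Sertoli libraries, and Wt1 at 44.0 ± 27.7 against 30.5 ± 20.7, differences within the spread between replicates (adjusted p = 0.123 and 0.321), although Wt1 was called higher in PTM without Sertoli replicate 2 (1.03). Gstm6 (-2.14) and Mro (-1.53) were lower in PTM, whereas Ptgds, a prostaglandin synthase, was higher (3.17), with an adjusted p of 0.0699 and a fold change of 3.298 at a pseudocount of 0.01.

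Cholesterol synthesis genes were higher in PTM, with 11 called higher and 0 lower of 22 adjusted over the list alone (adjusted p = 2.78e-06, and adjusted p = 0.599 with an estimated correlation). Among them were Acat2 (1.79), Sc5d (1.79) and Idi1 (1.60). Basement membrane and matrix genes had 5 called higher and 12 lower of 40 (adjusted p = 0.00104, and adjusted p = 0.308 with an estimated correlation). The collagen VI chains Col6a2 (-2.83) and Col6a1 (-2.50) were lower in PTM, and fibulin 2 (Fbln2, 2.28) was higher. Macrophage markers had 7 called higher and 0 lower of 14, and 9 higher adjusted over the list alone (adjusted p = 0.00166, and adjusted p = 0.68 with an estimated correlation), with Lyz2 at 42.7 ± 12.9 FPKM in PTM. Endothelial markers had 4 called higher and 0 lower of 13 (adjusted p = 3.85e-05, and adjusted p = 0.166 with an estimated correlation), and adipocyte markers 4 and 0 of 7 (adjusted p = 0.0206, and adjusted p = 0.308 with an estimated correlation). Receptors for contraction agonists were not called as a list (4 higher, 0 lower of 22, adjusted p = 0.271), although the adrenergic receptor Adra1d (3.61) and the vasopressin receptor Avpr1a (2.50) were higher in PTM.

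In limma, 876 genes were called between PTM and Sertoli libraries, 514 higher in PTM and 362 lower. The share called higher, 58.7%, became 49% after quantile normalization (423 higher, 440 lower) and 49.9% after median log-ratio scaling (428 and 430). Beyond the genes above, the largest changes were in the lipoprotein Apoc1 (5.89), the secreted Wnt modulator Sfrp2 (5.85), Rarres1 (5.49) and the kallikrein Klk1b24 (4.93), and, lower in PTM, Nrep (-3.13), Sorcs2 (-3.11), Col4a3 (-3.06) and Sytl2 (-3.06). The naming rule admits only genes in which all 3 libraries of one group lie above all 3 of the other, so that separation is no further evidence. In the authors' deposited table, a gene counted as called at q under 0.05 and an absolute log2 fold change of at least 1. By that rule, among the 13928 tested genes with a value there, it holds 1237 genes higher in PTM and 755 lower. These include 869 of the 876 in the same direction. Both sets of calls rest on the same libraries, so their overlap is not independent support. With the 6 libraries alone and replicate number as a block, a fit chosen after the data were seen, 299 genes were higher and 252 lower.

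Leydig cells sit outside the tubule and make androgen, and they share a mesenchymal origin with fibroblast-like cells of the interstitium. Claudin 11 (Cldn11) seals the junctions between Sertoli cells, Cst12 is a cystatin of Sertoli cells, and Gatm makes the precursor of creatine. Col3a1 and Dcn are a fibrillar collagen and a small proteoglycan of loose connective tissue, and the complement factors C4b and Cfb belong to innate defence. This comparison asks what parts PTM cells from the main cells of the interstitium.

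Against Leydig libraries the contractile list was higher in PTM, with 12 called higher and 0 lower of 25 adjusted over the list alone (adjusted p = 7.46e-08, and adjusted p = 0.142 with an estimated correlation). Acta2 was at 459 ± 184 FPKM in Leydig libraries, a log2 fold change of 1.88 (SE 0.28, adjusted p = 2.93e-05). Cnn1 differed by 4.25, Myh11 by 4.13, Actg2 by 4.05 and Des by 3.47. Regulators of smooth muscle transcription had 5 called higher and 0 lower of 20 (adjusted p = 0.0342, and adjusted p = 0.15 with an estimated correlation), among them Gata6 (1.96), Foxc1 (1.87) and Foxc2 (1.57). Sertoli markers had 16 called higher and 0 lower of 24, also adjusted over the list alone (adjusted p = 5.22e-06, and adjusted p = 0.264 with an estimated correlation). Cst12 (5.77), Cldn11 (4.96), Defb36 (4.72) and Dmrt1 (3.86) differed most, and Sox9 was at 36.6 ± 21.4 FPKM in PTM and 1.95 ± 0.751 in Leydig libraries. Endothelial markers (5 higher, 0 lower of 13, adjusted p = 0.000736, and adjusted p = 0.171 with an estimated correlation) and cell cycle genes (6 higher, 0 lower of 30, adjusted p = 0.00946, and adjusted p = 0.692 with an estimated correlation) were higher as well. The cell cycle count rested on single libraries, with 1 called higher without Leydig replicate 3 and 17 without Leydig replicate 1.

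Fibroblast markers were lower in PTM, with 0 called higher and 13 lower of 17 adjusted over the list alone (adjusted p = 2.11e-12, and adjusted p = 0.000205 with an estimated correlation). Clec3b (-4.03), Cd34 (-3.94) and Dcn (-3.91) led this list. Matrix genes had 2 called higher and 18 lower of 40 (adjusted p = 5.22e-06, and adjusted p = 0.146 with an estimated correlation), with Col3a1 at 164 ± 63.8 FPKM in PTM and 1736 ± 429 in Leydig libraries (log2 fold change -3.45). Gonadal and organ position factors had 0 called higher and 6 lower of 26 (adjusted p = 0.000602, and adjusted p = 0.171 with an estimated correlation), Tcf21 by -3.35. Sex steroid and nuclear receptors had 1 called higher and 4 lower of 20 (adjusted p = 0.00674, and adjusted p = 0.146 with an estimated correlation), including Thra (-1.55) and Pgr (-1.34). Hox genes had 0 higher and 4 lower of 28 (adjusted p = 0.0168, and adjusted p = 0.69 with an estimated correlation), led by Hoxd9 (-1.67), and 2 lower without PTM replicate 2. Innate immune sensing (0 higher, 3 lower of 24, adjusted p = 0.0133, and adjusted p = 0.264 with an estimated correlation) and cholesterol synthesis (0 higher, 1 lower of 22, adjusted p = 0.00488, and adjusted p = 0.69 with an estimated correlation) were shifted by small amounts. Without Leydig replicate 2, 3 cholesterol synthesis genes were called lower. Under median log-ratio scaling these last calls and that of the nuclear receptors were lost (adjusted p = 0.058, 0.058 and 0.0758).

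Leydig markers were not called as a list against the Leydig libraries themselves. Insl3 was at 3647 ± 1394 FPKM in PTM and 3249 ± 3138 in Leydig libraries (log2 fold change 0.61, adjusted p = 0.53), and Cyp11a1 at 300 ± 94.9 against 214 ± 93.9 (0.52, adjusted p = 0.326), differences within the spread between replicates. Akr1cl, a reductase of the aldo-keto family, was lower in PTM (183 ± 47.0 against 596 ± 148 FPKM, log2 fold change -1.70), with an adjusted p of 0.136 and a fold change of -1.705 at a pseudocount of 0.01. In limma, 1603 genes were called, 943 higher in PTM and 660 lower. The share called higher, 58.8%, became 46% after quantile normalization and 38% after median log-ratio scaling, which moved the median log2 fold change of all genes by -0.11 and -0.23. Gatm (5.75), Tex19.2 (5.16), Edn1 (4.91) and Ttyh1 (4.84) were among the largest increases. Ifitm1 (-5.74), Igfbp4 (-5.54), C4b (-5.28), Cfb (-4.72), Adgrd1 (-4.43) and Ly6c1 (-4.43) were among the largest decreases. Igfbp4 (Entrez 16010, chromosome 11, 99041260 to 99052646, plus strand) was at 46.4 ± 18.9 FPKM in PTM and 2107 ± 522 in Leydig libraries. At the cut-offs given above, the authors' deposited table calls 1866 higher in PTM and 1111 lower, of 13910 tested genes with a value. These include 1591 of the 1603 in the same direction.

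Germ cells pass from mitosis through meiosis to the condensed spermatid. Ddx4 is an RNA helicase of the germ line, Ldhc a lactate dehydrogenase of spermatocytes, Ybx2 a binder of stored messenger RNA, and the protamines Prm1 and Prm2 replace histones in sperm. This comparison sets a somatic cell of the tubule wall against the cells it surrounds. Of the spermatid markers, 0 were called higher and 25 lower in PTM of 25 tested, with the same numbers adjusted over the list alone (adjusted p = 4.08e-12, and adjusted p = 0.031 with an estimated correlation). Of the spermatocyte markers, 1 was called higher and 21 lower of 22 (adjusted p = 7.61e-09, and adjusted p = 0.00893 with an estimated correlation). Ldhc (Entrez 16833, chromosome 7, 46861263 to 46878142, plus strand) was at 1.12 ± 0.396 FPKM in PTM and 3637 ± 76.0 in germ cells (log2 fold change -10.76, SE 0.18). Prm1 stood at 3.33 ± 1.24 FPKM in PTM and 2697 ± 156 in germ cells (-9.33), and Ddx4 at 0.427 ± 0.106 against 225 ± 17.3 (-7.30). Ybx2 (-10.16), Dkkl1 (-10.05), Fhl4 (-9.92) and the tubulins Tuba3a and Tuba3b, whose near-identical reads are hard to assign to one gene, were also among the largest decreases. Hoxa4 was at 137 ± 11.7 FPKM in germ cells and 0.270 ± 0.125 in PTM.

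Matrix genes were higher in PTM than in germ cells, with 37 called higher and 1 lower of 40 adjusted over the list alone (adjusted p = 3.3e-05, and adjusted p = 0.16 with an estimated correlation). Niche factors secreted by the tubule wall had 29 called higher and 0 lower of 32 (adjusted p = 0.000227, and adjusted p = 0.031 with an estimated correlation), among them Csf1 (7.95) and Adm (7.51). The contractile list had 21 called higher and 2 lower of 25 (adjusted p = 0.000227, and adjusted p = 0.172 with an estimated correlation), with Acta2 at 1.77 ± 1.21 FPKM in germ cells (9.29). Interferon-stimulated genes had 30 called higher of 31 (adjusted p = 0.000172, and adjusted p = 0.525 with an estimated correlation), innate immune sensing 20 of 24 (adjusted p = 0.00775, and adjusted p = 0.172 with an estimated correlation) and sex steroid and nuclear receptors 13 of 20 (adjusted p = 0.0405, and adjusted p = 0.172 with an estimated correlation), none lower. Contraction agonist receptors had 13 called higher and 2 lower of 22 (adjusted p = 0.0405, and adjusted p = 0.206 with an estimated correlation). Sertoli markers (20 higher, 1 lower of 24, adjusted p = 0.0176, and adjusted p = 0.525 with an estimated correlation) and Leydig markers (14 higher, 0 lower of 14, adjusted p = 0.0164, and adjusted p = 0.411 with an estimated correlation) completed the lists called higher. The nuclear receptor call was lost after quantile normalization (adjusted p = 0.0572). In limma, 10180 genes were called, 6193 higher in PTM and 3987 lower, and the median log2 fold change of all genes was 0.62, which rescaling moved by -0.35 (quantile) and -0.44 (median log-ratio). Timp1 (9.45), Cryab (9.16), Anxa1 (8.96) and Ctgf (8.89) were the largest increases besides Acta2. At the same cut-offs, and among 14425 tested genes with a value there, the authors' deposited table calls 7126 higher in PTM and 4277 lower. These include 10173 of the 10180 in the same direction.

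**Figure D2:**
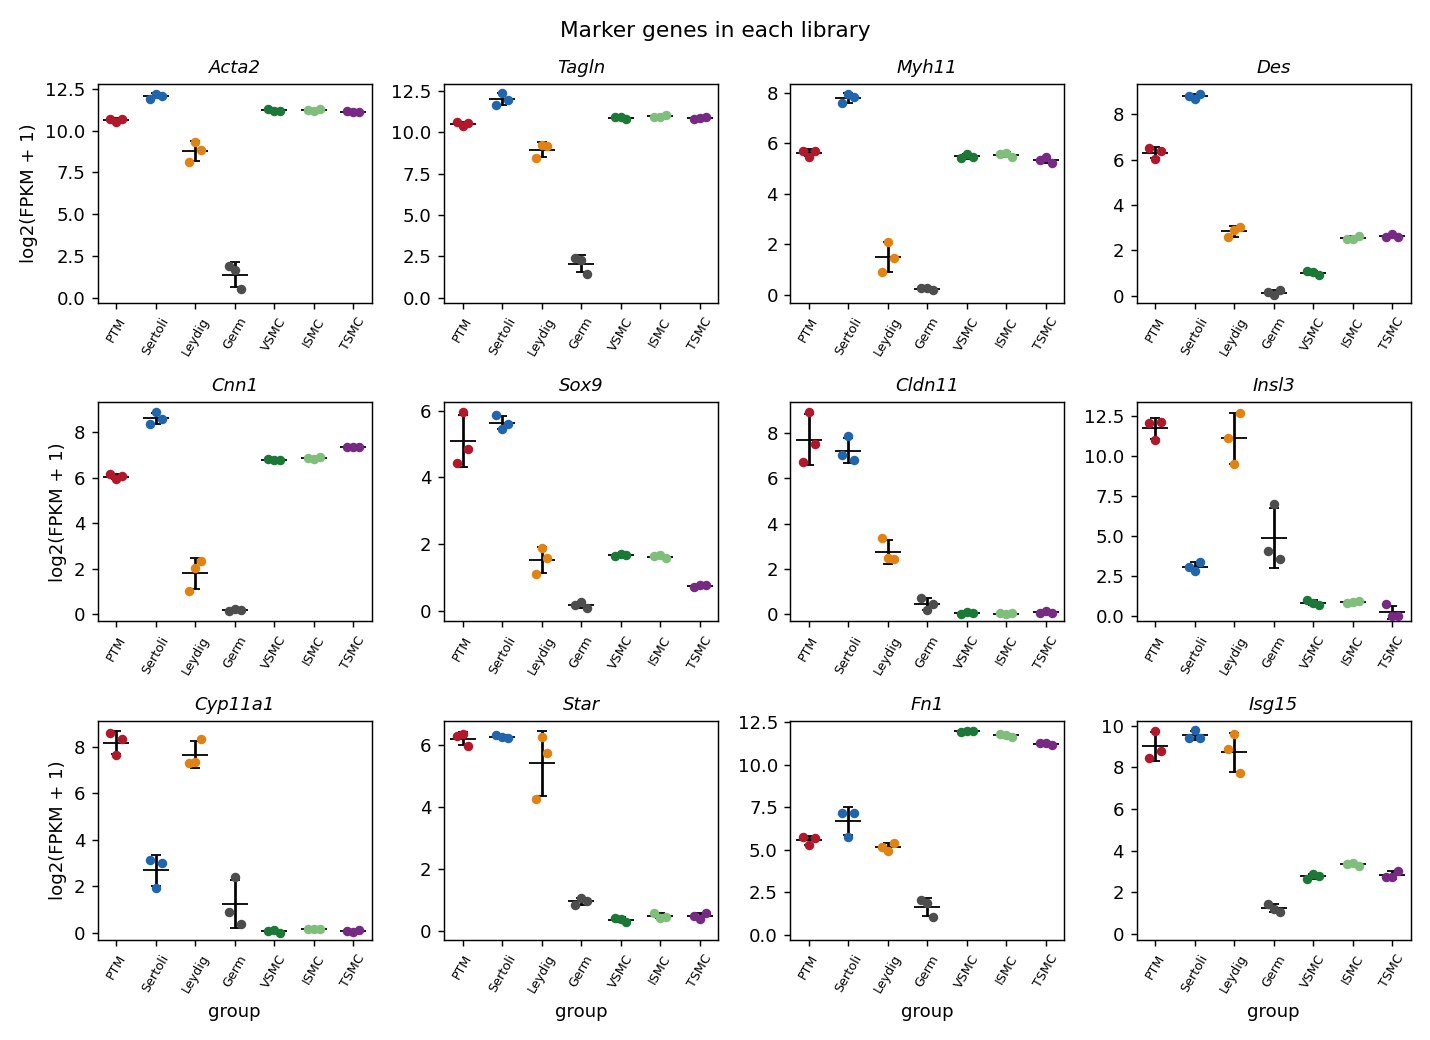
log2(FPKM + 1) of 12 genes in the 7 groups, each point a library, with lines and bars for the mean and SD of 3 libraries. Acta2, Myh11, Des and Cnn1 are higher in Sertoli than in PTM libraries, Insl3 and Cyp11a1 are within the replicate spread of each other in PTM and Leydig libraries, and Fn1 is highest in the smooth muscle groups.

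Smooth muscle of vessels, gut and airways uses the same contractile genes as PTM cells, but it develops from other mesenchyme and is embedded in elastic and fibronectin-rich matrix. Fibronectin (Fn1), elastin (Eln) and periostin (Postn) are structural proteins of that matrix, and Grem1 binds and blocks bone morphogenetic proteins. The Hox genes mark position along the body axis, and Gata4 and Nr5a1 are transcription factors of the somatic gonad. Isg15 and Irf7 belong to the response to type I interferon. These comparisons ask what sets PTM cells apart from smooth muscle of other organs.

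The contractile list did not differ as a whole from any smooth muscle group. It had 4 members called higher and 3 lower against VSMC (adjusted p = 0.263), 4 and 3 against ISMC (adjusted p = 0.255) and 5 and 4 against TSMC (adjusted p = 0.507), of 25 tested in each case and with the same numbers adjusted over the list alone. The median log2 fold change of the members was -0.16, -0.20 and -0.26 while the mean was 0.13, 0.03 and 0.22, so the sign of the list depended on the summary. Acta2 was at 2366 ± 87.0 FPKM in VSMC, 2404 ± 77.8 in ISMC and 2217 ± 43.8 in TSMC, log2 fold changes of -0.56, -0.58 and -0.47 that did not pass (adjusted p = 0.0903, 0.0809 and 0.16). Myh11 differed by 0.14, 0.08 and 0.28 (adjusted p = 0.544, 0.755 and 0.217). Des was higher in PTM, by 5.31, 3.77 and 3.67, as was the myosin light chain kinase Mylk, by 2.55, 2.35 and 1.52. Filamin A (Flna) was lower by -1.59, -1.51 and -1.43, Actg2 by -1.44, -1.53 and -1.10, and Cnn1 by -1.30 against TSMC. Against VSMC and ISMC, Cnn1 was called only after rescaling (-1.06 and -1.10 with quantile normalization).

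Regulators of smooth muscle transcription were lower in PTM, with 1 called higher and 7 lower of 20 against VSMC, 0 and 6 against ISMC and 0 and 6 against TSMC, adjusted over the list alone. These calls (adjusted p = 1.62e-05, 3.78e-06 and 0.00046) held with an estimated correlation (adjusted p = 0.00956, 0.00514 and 0.0389). Foxc2 was lower by -2.92, -2.84 and -1.92, and Tbx18 by -1.96, -1.88 and -1.42. Foxf1 was lower against TSMC alone (-4.13). Whether the fold changes differ between the 3 comparisons was not tested.

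Hox genes had 6 called higher and 21 lower of 28 against VSMC and the same numbers against ISMC, adjusted over the list alone (adjusted p = 9.61e-11 and 8.24e-10, and adjusted p = 0.137 and 0.147 with an estimated correlation). Against TSMC 10 were higher and 13 lower (adjusted p = 0.0488, and adjusted p = 0.73 with an estimated correlation), a call also lost under both rescalings (adjusted p = 0.31 and 0.485). Hoxd9 and Hoxd10 were higher in PTM than in all 3 groups, by 3.89, 3.99 and 4.56 and by 4.14, 4.11 and 4.14. Hoxa5 (-4.16, -3.94 and -3.96) and Hoxb8 (-4.03, -3.92 and -1.96) were lower. Hoxc6 was lower than in VSMC (-1.39) and ISMC (-1.10) and higher than in TSMC (3.34). Among gonadal and organ position factors, Gata4 was higher by 5.85, 5.75 and 5.02 and Nr5a1 by 5.82, 5.82 and 5.75. As a list these were called only against TSMC (7 higher, 10 lower of 26, adjusted p = 0.0224, and adjusted p = 0.383 with an estimated correlation), where the median was -0.34 and the mean 0.26. Quantile normalization removed that call (adjusted p = 0.169), as did median log-ratio scaling (0.274).

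**Figure D3:**
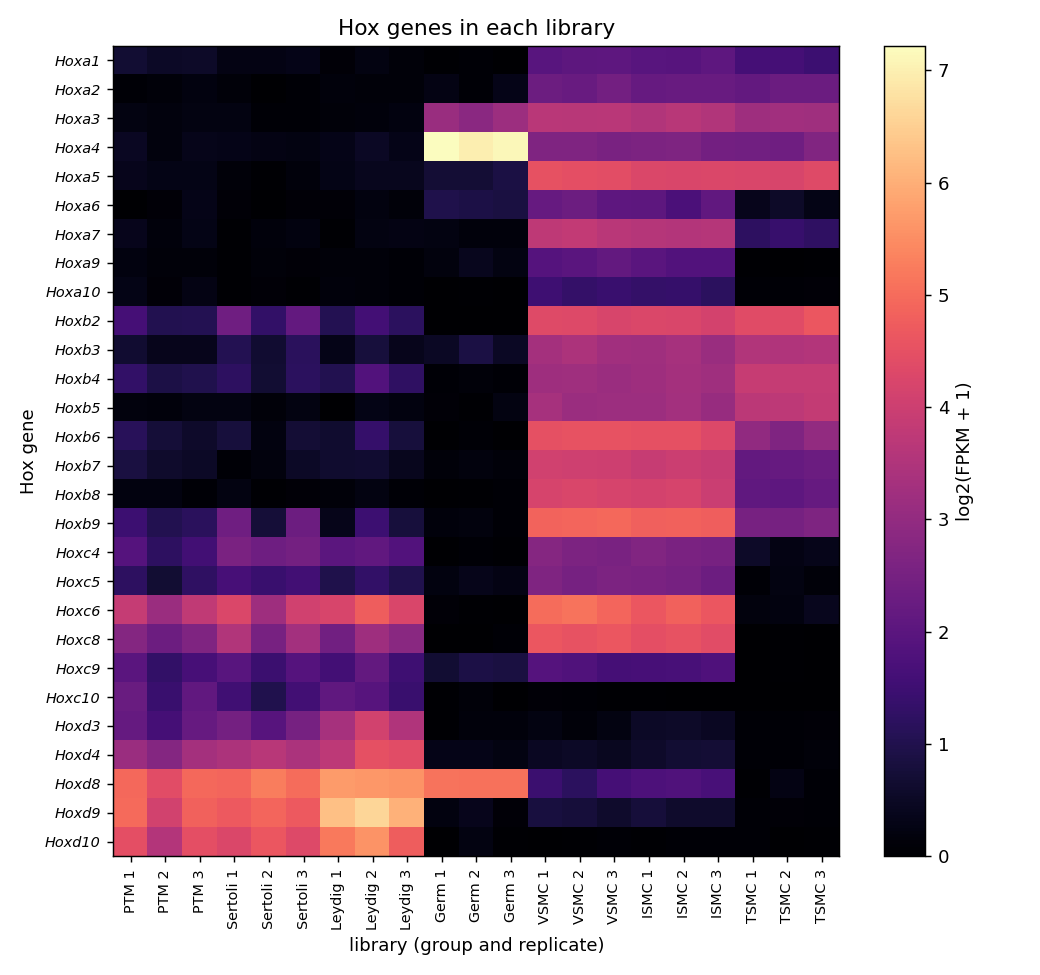
log2(FPKM + 1) of the 28 tested Hox genes in each of the 21 libraries. PTM, Sertoli and Leydig libraries share high Hoxd8, Hoxd9 and Hoxd10, whereas VSMC and ISMC share one pattern and TSMC has another.

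Interferon-stimulated genes were higher in PTM, with 30 called higher and 0 lower of 31 in each of the 3 comparisons, adjusted over the list alone (adjusted p = 1.28e-10, 2.03e-10 and 1.07e-11 for VSMC, ISMC and TSMC, and adjusted p = 0.383, 0.308 and 0.356 with an estimated correlation). Isg15 (Entrez 100038882, chromosome 4, 156199424 to 156200818, minus strand) was at 557 ± 280 FPKM in PTM, 5.80 ± 0.603 in VSMC, 9.13 ± 0.552 in ISMC and 6.12 ± 0.926 in TSMC. Sertoli (753 ± 119) and Leydig (485 ± 283) libraries lay within the replicate spread of PTM (adjusted p = 0.276 and 0.552). Sertoli markers had 20 called higher and 0 lower of 24 each time (adjusted p = 9.43e-08, 6.73e-08 and 4.86e-08, and adjusted p = 0.234, 0.191 and 0.206 with an estimated correlation). Leydig markers had 11 called higher and 0 lower of 14 each time (adjusted p = 3.5e-05, 1.14e-05 and 4.55e-06, and adjusted p = 0.272, 0.191 and 0.206 with an estimated correlation). Insl3 exceeded the smooth muscle groups by 10.89, 10.86 and 11.50, Cyp11a1 by 8.11, 8.01 and 8.10, the protease-like Prss35 by 8.41, 8.28 and 8.33, and the chaperone Clu by 7.69, 7.42 and 8.15.

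Matrix genes were lower in PTM, with 7 called higher and 20 lower of 40 against VSMC, 6 and 21 against ISMC and 5 and 22 against TSMC (adjusted p = 2.56e-06, 3.03e-07 and 4.77e-07, and adjusted p = 0.131, 0.0853 and 0.0881 with an estimated correlation). Fn1 (Entrez 14268, chromosome 1, 71585473 to 71653234, minus strand) was at 46.4 ± 8.23 FPKM in PTM, 3991 ± 142 in VSMC, 3388 ± 178 in ISMC and 2409 ± 84.1 in TSMC. Its log2 fold changes were -6.41, -6.17 and -5.68 (SE 0.29). Eln was lower by -6.23, -6.18 and -3.64, Postn by -5.46, -5.55 and -5.20, and Grem1 by -6.23, -6.37 and -8.52. Niche factors were called against TSMC only (9 higher, 11 lower of 32, adjusted p = 0.0412, and adjusted p = 0.206 with an estimated correlation), a call lost under both rescalings (adjusted p = 0.228 and 0.476). Against VSMC 10 niche factors were higher and 9 lower, or 11 and 9 adjusted over the list alone, with the stem cell factor Kitl higher in PTM by 4.16 and Grem1 lower.

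Endothelial markers were lower in PTM than in VSMC (1 higher, 9 lower of 13, adjusted p = 7.73e-06, and adjusted p = 0.131 with an estimated correlation) and ISMC (1 higher, 8 lower, adjusted p = 3.09e-05, and adjusted p = 0.135 with an estimated correlation), but not called against TSMC (adjusted p = 0.741). Emcn was at 18.5 ± 2.05 FPKM in PTM, 126 ± 7.81 in VSMC and 124 ± 4.79 in ISMC. Glial and neuronal markers were lower than in ISMC (1 higher, 6 lower of 10, adjusted p = 4.46e-05, and adjusted p = 0.0199 with an estimated correlation) and TSMC (1 higher, 4 lower, adjusted p = 0.000368, and adjusted p = 0.0389 with an estimated correlation), with Sox10 at 20.1 ± 2.63 FPKM in ISMC and 27.1 ± 0.416 in TSMC. Macrophage markers were lower than in ISMC (0 higher, 7 lower of 14, adjusted p = 0.00181, and adjusted p = 0.497 with an estimated correlation; adjusted p = 0.0517 after median log-ratio scaling) and higher than in TSMC (11 higher, 1 lower, adjusted p = 0.0357, and adjusted p = 0.748 with an estimated correlation). Markers of interstitial cells of Cajal had 0 higher and 1 lower of 4 against VSMC (adjusted p = 0.00989, and adjusted p = 0.137 with an estimated correlation) and ISMC (adjusted p = 0.0121, and adjusted p = 0.147 with an estimated correlation). Mesothelial markers were called against ISMC (1 higher, 3 lower of 9, adjusted p = 0.0428, and adjusted p = 0.191 with an estimated correlation) but not after rescaling (adjusted p = 0.167 and 0.307). Cholesterol synthesis was called lower against VSMC (1 higher, 5 lower of 22, adjusted p = 0.0111, and adjusted p = 0.655 with an estimated correlation) but not after rescaling (adjusted p = 0.0768 and 0.163).

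In limma, 2743 genes were called against VSMC (1823 higher in PTM, 920 lower), 2550 against ISMC (1539 and 1011) and 2677 against TSMC (1637 and 1040). The share called higher depended on scaling. It was 66.5% against VSMC, 60.4% against ISMC and 61.2% against TSMC, but 45.4, 44.1 and 45.9% after quantile normalization and 43.9, 40.1 and 45.1% after median log-ratio scaling. Those scalings moved the median log2 fold change by -0.19 and -0.30, by -0.14 and -0.26, and by -0.14 and -0.23. Thy1 (-7.03 and -6.92) and Aqp1 (-5.96 and -5.92) were further large decreases against VSMC and ISMC. Acta1 (-7.42), Col10a1 (-6.76), Mgp (-5.83) and Ngfr (-5.72) were large decreases against TSMC. Cxcl14 (8.25 and 7.79 against VSMC and ISMC), Lcn2 (7.86 and 7.64 against VSMC and TSMC) and Sfrp2 (7.78 against TSMC) were further large increases. The same cut-offs were applied to the authors' deposited table, among tested genes with a value there. For VSMC it calls 3344 genes higher in PTM and 1406 lower of 13843. Its numbers are 2762 and 1588 of 13896 against ISMC, and 2860 and 1533 of 13957 against TSMC. These include 2740 of the 2743, 2545 of the 2550 and 2671 of the 2677 in the same direction.

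**Figure D4:**
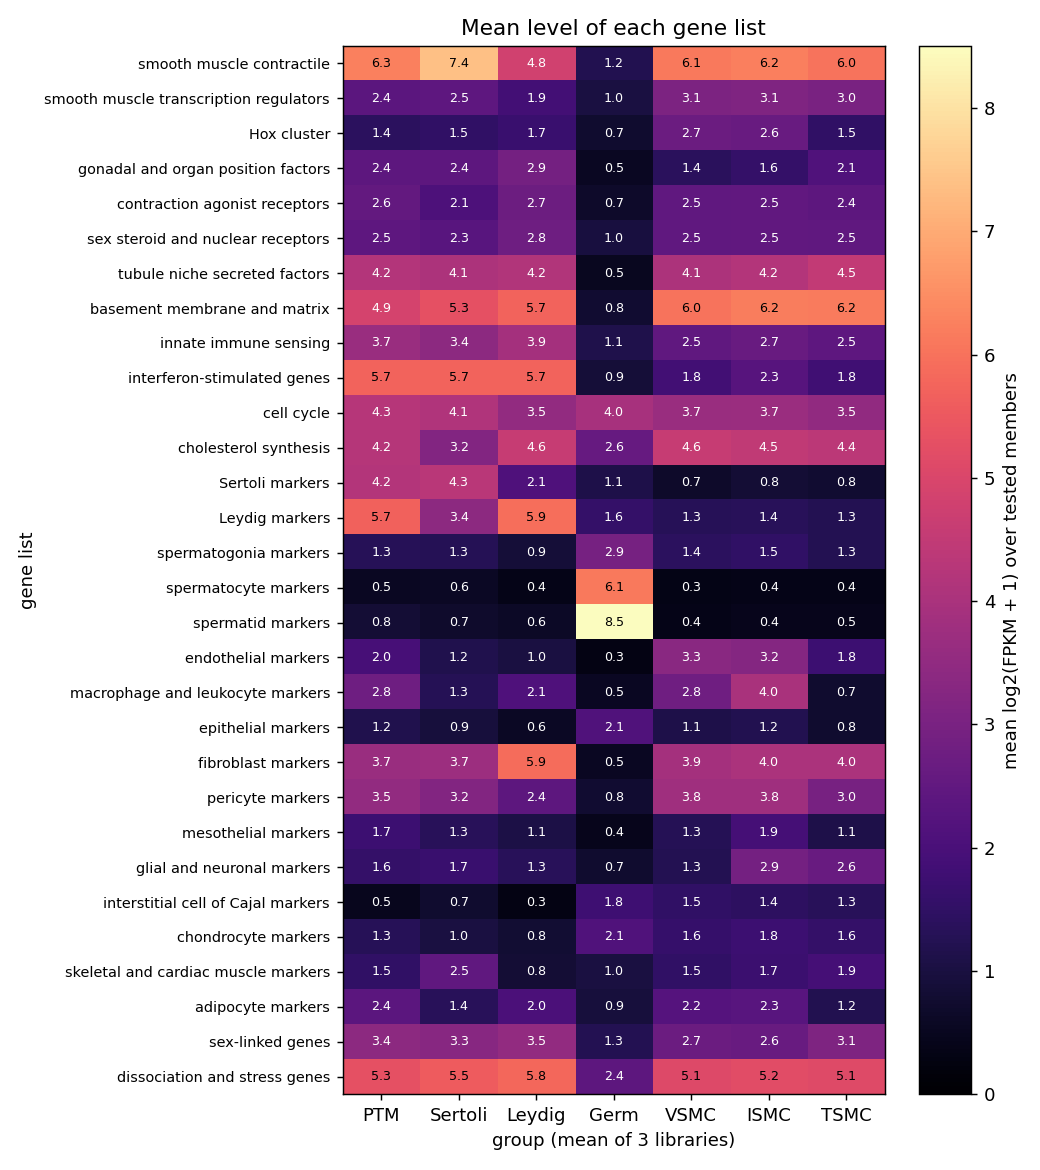
Mean log2(FPKM + 1) over the tested members of 30 gene lists in the 7 groups, with the value printed in each cell. Interferon-stimulated genes average 5.745 in PTM and 1.814 to 2.267 in the smooth muscle groups, and the contractile list 6.251 in PTM and 7.403 in Sertoli libraries.

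Stc1 encodes a glycoprotein hormone, Pacsin3 a membrane-bending protein, Hpgd the enzyme that inactivates prostaglandins, and Angpt2 a ligand of endothelial receptors. The question here was which genes mark PTM against every other group. In limma, 34 genes were higher in PTM than in all 6 groups, against a mean of 0.68 and a maximum of 4 in 50 simulations of unchanged groups. Without Sertoli replicate 2 the number was 71, and without PTM replicate 1 it was 61. The real groups differ widely, so a count above these simulations does not show that such a set is particular to PTM. Under shuffled labels, the PTM label on the 3 TSMC libraries gave 38 such genes. The other labels were shuffled as well, so 38 is not a count against the real groups and cannot be set beside 34. Stc1 (Entrez 20855, chromosome 14, 69029289 to 69041401, plus strand) was at 58.1 ± 10.0 FPKM in PTM and nearest in Leydig libraries, with a smallest log2 fold change of 2.17. Pacsin3 was at 80.8 ± 8.88 FPKM (smallest fold change 1.78, chromosome 2, 91256165 to 91264680) and Hpgd at 90.3 ± 13.7 (1.74, chromosome 8, 56294552 to 56321046). Others named under the same rule, which leaves out genes under 10 FPKM or with overlapping libraries, were Tslp (1.48), Tmem35 (1.41) and Angpt2 (1.24), and Kcnk1, Tpd52l1, Car12, Bdh1 and Tspan8 between 1.22 and 1.03. Stc1, Pacsin3, Hpgd and Tmem35 stayed in the set in all 32 settings tried. Angpt2 fell short against VSMC after median log-ratio scaling (0.941), and Tslp and the last 5 genes left the set in at least 2 settings each.

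No gene was lower in PTM than in all 6 groups in limma, where 0 passed with the size criterion at an unadjusted p under 0.05 and 51 did without it. Without Leydig replicate 3 the number was 2. The genes higher in PTM and in each smooth muscle group than in each of Sertoli, Leydig and germ cells numbered 12, against 0 in all 50 simulations. Without PTM replicate 2 there were 21. These simulations too held unchanged groups, so the count above them shows only that the groups differ. Of the 12 genes, 11 are named because the number is small, chosen after their values were seen: Pcdh1, Emcn, Ctla2b, Crct1, Pmaip1, Acan, Gprc5a, Prkar2b, Sncg, Tns3 and Nuak1. Their smallest log2 fold changes over the 12 comparisons ran from 1.05 in Nuak1 to 1.70 in Pcdh1, a protocadherin of cell adhesion. Emcn codes for a sialomucin of endothelium, and Acan for the aggrecan core protein. The endothelial markers as a list had the same order, with a mean log2(FPKM + 1) of 1.957 in PTM, 3.323 in VSMC, 3.233 in ISMC and 1.757 in TSMC. It was 1.195 in Sertoli, 0.998 in Leydig and 0.322 in germ cells. Whether the shared genes come from contractile or other cells was not tested. None of the 12 was on the contractile list, which follows from the Sertoli comparison, where 0 of its members were called higher in PTM.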

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

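The fits with a variance for each group, with each smooth muscle group as 1 sample, without replicate 2 of PTM, Sertoli and germ cells together, and with PTM and Sertoli alone under a replicate block were chosen only after the data were seen, as was leaving out libraries for the correlations. The other alternatives were written earlier.

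A smaller pseudocount raised the counts, since it widens fold changes of weakly expressed genes. With 0.1, 922 genes were higher and 558 lower in PTM than in Sertoli, and 1607, 2786 and 2323 were higher than in Leydig, VSMC and ISMC. With 0.01 these numbers were 938 and 555, and 1761, 3057 and 2490, with 2596 higher than in TSMC. Dropping the minimum fold gave 2738 higher and 1450 lower against Sertoli, 5044 and 2350 against Leydig, 6355 and 2852 against VSMC, 5853 and 3008 against ISMC, and 5798 and 3105 against TSMC.

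Rescaling moved counts from higher to lower. Against VSMC quantile normalization gave 1190 higher and 1432 lower, and median log-ratio scaling 1144 and 1460. Median log-ratio scaling left 603 genes higher than in Leydig and 1013 higher than in ISMC. The shift of the median fold change under each scaling is the cause by construction.

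Replicate number as a block over all groups gave 509 higher and 358 lower against Sertoli. With the 6 PTM and Sertoli libraries alone, the block gave 299 higher and 252 lower, against 384 and 295 in the same libraries without it. Fewer libraries estimate the spread there, and the smooth muscle libraries, which vary least, are not among them.

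The set higher in PTM than all 6 groups had 34 genes. It had 53 with a pseudocount of 0.1 (31 of the 34 among them), 37 with 0.01 (24 of the 34 among them), 17 with a filter of 5 FPKM because fewer genes were tested, 21 after quantile normalization (20 of them among the 34), 20 after median log-ratio scaling (all among the 34), 54 without replicate 2 of PTM, Sertoli and germ cells together, and 381 with no minimum fold. The set lower than all 6 groups, 0 genes, had 7 and 17 with the pseudocounts 0.1 and 0.01, 4 after quantile normalization, 3 after median log-ratio scaling, 1 without replicate 2 of those groups, and 41 with no minimum fold. The 12 genes shared with smooth muscle became 52 and 53 with the smaller pseudocounts, 24 without replicate 2 of those groups and 303 with no minimum fold. The cause of the increase without replicate 2 was not tested.

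With an estimated correlation 0 lists were called higher and 1 lower against Sertoli, 0 and 1 against Leydig, 0 and 1 against VSMC, 0 and 2 against ISMC, and 0 and 2 against TSMC. Against germ cells 1 was higher. The estimated correlation exceeded the preset 0.01 in interferon-stimulated genes (0.684), cholesterol synthesis (0.592) and Hox genes (0.308), and all their calls were lost. At the preset, genes that vary together are treated as nearly independent. A higher correlation does not account for every loss, since regulators of smooth muscle transcription, at 0.008, also lost their call against Leydig. How much of the loss comes from the correlation was not tested. Against germ cells 14 lists were higher with a pseudocount of 0.1 and 15 with no filter. With a filter of 5 FPKM 2 lists were lower against Sertoli, median log-ratio scaling gave 4 lower against Leydig and 5 higher against ISMC, and 3 lists were lower against TSMC under each rescaling and without replicate 2 of PTM, Sertoli and germ cells. The cause was not tested. Of 180 list tests, 128 kept their side of the threshold with an estimated correlation and 161 to 178 of the 180 under the pseudocounts, scalings, replicate block and no filter. No called list reversed.

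Spearman correlation of PTM was 0.956 with Sertoli and 0.183 with germ cells. Over the 2000 most variable genes Pearson correlation was 0.949 with Sertoli, 0.81 with VSMC, 0.824 with ISMC and 0.812 with TSMC, and it reversed to -0.702 with germ cells. These genes were chosen because they vary between libraries, and how many of them separate germ cells from the rest was not counted.

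Leaving out 1 library at a time gave 442 to 706 genes higher and 332 to 437 lower against Sertoli, 875 to 1152 and 581 to 720 against Leydig, and 6146 to 6241 and 3970 to 4001 against germ cells. The ranges were 1789 to 1860 and 899 to 940 against VSMC, 1519 to 1565 and 993 to 1045 against ISMC, and 1616 to 1672 and 1009 to 1059 against TSMC. The set higher than all 6 groups ranged from 25 to 71 genes, highest without Sertoli replicate 2 (71) and without PTM replicate 1 (61). The set lower than all ranged from 0 to 2, with 2 without Leydig replicate 3, and the shared set from 11 to 21, with 21 without PTM replicate 2. Correlations ranged from 0.957 to 0.962 with Sertoli, 0.931 to 0.943 with Leydig, 0.189 to 0.194 with germ cells, 0.883 to 0.892 with VSMC, 0.889 to 0.897 with ISMC and 0.881 to 0.891 with TSMC.

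Of 824 fold changes of named genes, 772 kept their side of the threshold under median log-ratio scaling, 781 under quantile normalization, 781 and 773 under the smaller pseudocounts and 824 with the replicate block, and none that was called reversed. Over all fits without 1 library, 4804 kept it, 54 gained a call and 86 lost one. A variance for each group gave 33 and 12 genes in the sets higher in PTM and shared with smooth muscle, and smooth muscle groups as 1 sample each gave 25 and 11. With about 21500000 fragments per library, genes near 1 FPKM rest on few reads, and a difference in them was not always detectable at this depth.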

Other observations

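The tests of mixed cells, exchanged labels and a shared smooth muscle population were chosen only after the results were seen, whereas the rescaling test and the counts of other splits were written earlier. The sets of genes for the mixture tests were redefined after a first look, from genes picked because they were called lower in PTM to all genes of the list at 10 FPKM or more in the source group. The first medians were 0.087 for Leydig and 0.306 for Sertoli makeup, and the latter would have argued against admixed Sertoli cells where the later value leaves them undecided.

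Among genes with a known part in the testis, the stem cell factor Kitl was at 49.8 ± 10.3 FPKM (SD, n = 3) in PTM, 50.3 ± 5.68 in Leydig, 15.7 ± 0.909 in Sertoli and 1.80 ± 0.272 in VSMC libraries. Gdnf, a growth factor for spermatogonial stem cells, was at 16.2 ± 10.9 FPKM in PTM, 14.3 ± 1.94 in Sertoli, 0.277 ± 0.150 in Leydig and 6.42 ± 0.312 in TSMC libraries. Bmp2 stood at 6.15 ± 1.10 FPKM in PTM and 0.670 ± 0.171 in Sertoli libraries, a log2 fold change of 2.09. Several lists were not called by limma's camera in any comparison: spermatogonia (2 called higher and 7 lower of 12 against germ cells, adjusted p = 0.0781), epithelial, pericyte, chondrocyte and sex-linked genes, and dissociation and stress genes (2 higher and 9 lower of 20 against Leydig, adjusted p = 0.084, with 1 and 4 without Leydig replicate 2, 4 and 6 without Leydig replicate 3 and 4 and 8 without PTM replicate 1, and 17 higher and 1 lower against germ cells, adjusted p = 0.0563). Of the 6 erythroid markers with FPKM values, 0 passed the filter.

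Among the smooth muscle groups, 120 genes were called between VSMC and ISMC, 662 between VSMC and TSMC and 602 between ISMC and TSMC, against 876 between PTM and Sertoli and 1860 between Sertoli and Leydig. Of 28 Hox genes, 0 were called between VSMC and ISMC (limma) and 14 between each of them and TSMC. The genes that separated ISMC from VSMC were chosen after their values were seen. They include the neural crest genes Ngfr (54.6 against 0.117 FPKM) and Sox10 (20.1 against 0.0267), and the macrophage genes Marco (20.6 against 0.987) and Apoe (log2 fold change, VSMC minus ISMC, -2.36). Des (4.83 against 1.01 FPKM), Hand2 (5.33 against 0.407) and Foxf1 (1.89 against 0.397) were also called.

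Tested markers of Leydig and Sertoli cells were present in PTM libraries at levels like those of the Leydig and Sertoli libraries. The median ratios were 0.82 over 14 Leydig markers and 0.826 over 22 Sertoli markers. The Leydig list has 20 genes, and those below the filter do not enter its ratio. Cyp17a1 was below the filter, at a mean of 0.05 FPKM in the Leydig libraries themselves, so the match does not extend to such genes. Lhcgr and Hsd17b3, also below the filter, were at 0.187 and 0.35 FPKM in the Leydig libraries. Fibroblast markers averaged 5.887 in Leydig and 3.654 in PTM libraries on the log2(FPKM + 1) scale. A match to these libraries is therefore not shown to be a match to Leydig cells. Admixed cells with the makeup of the Leydig libraries would bring the abundant fibroblast genes along, but these were present at a median ratio of 0.11, which argues against such cells as the whole cause. Of the contractile list, 0 members were higher in the libraries labelled Leydig, which argues against exchanged PTM and Leydig labels only if contractile genes mark PTM cells. The list was higher in Sertoli than in PTM libraries, so that premise is open and the labels are not settled by it. Admixed cells with the makeup of the Sertoli libraries may remain part of the cause, since contractile genes abundant in Sertoli libraries were present in PTM at a ratio of 0.45, below the Sertoli markers but not far enough to decide. Cells of other makeup than these libraries, and expression by PTM cells themselves, were not tested.

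Contractile genes were higher in Sertoli than in PTM libraries, the reverse of what their names lead one to look for. Rescaling does not account for it, since 14 members were still called lower in PTM after median log-ratio scaling. Cells with the makeup of the PTM libraries mixed into the Sertoli libraries cannot alone raise a gene above its PTM level, and the median Sertoli to PTM ratio over contractile members was 2.22, which restates the pattern and is not a separate test. Exchanged PTM and Sertoli labels cannot be told apart from correct ones by these data, since Sertoli markers differed by a median of only -0.32 on the log2 scale. Contractile cells purer than the PTM libraries in the Sertoli preparations, or contractile genes raised in cultured Sertoli cells, may also explain it and were not tested.

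VSMC and ISMC libraries were nearly alike, with a mean correlation of 0.993 between groups against 0.998 within each. A candidate explanation is one shared cell population with more cells of other types in ISMC, and of the 120 genes called between them 0% were higher in VSMC, which that explanation needs. The 120 include Des, of the contractile list, and whether such genes differ within the muscle cells themselves was not tested. A library carrying the label of the other group is argued against, as 0 of the 6 libraries correlated best with a library of the other group. A common response of smooth muscle from different organs to culture was not tested.

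Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. Real values and the highest of the others were 876 and 201 for Sertoli, 1603 and 39 for Leydig, 10180 and 0 for germ cells, 2743 and 0 for VSMC, 2550 and 0 for ISMC and 2677 and 0 for TSMC. For PTM and Sertoli, where same-numbered libraries went together, the 3 other splits that part all 3 pairs reached 32 at most, and the 6 that part 1 pair reached 201. Over 100 labelings of the 21 libraries, 2 gave at least the 34 genes higher in PTM than all groups. The other of these, with 38 genes, gave the PTM label to the 3 TSMC libraries. Its other labels were shuffled as well, so its genes were not set against the real groups. A labeling that mixes cell types under the PTM label leaves almost no gene to call. The count of labelings therefore shows only that the groups differ, and nothing on chance is claimed from it. The same holds for the 12 genes shared with smooth muscle, where 1 labeling, the real one, gave as many and the highest other was 0. For the set lower than all groups the real count was 0 (limma), which all 100 labelings reach by construction (highest other 1), so that count decides nothing.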
